A study of Mus musculus with 4 samples.

How the data were processed

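RNA from Th2 cells, the CD4 helper T cell type that makes IL-4, IL-5 and IL-13, was measured by RNA sequencing in 4 libraries from C57BL/6 mice. Splenic CD4 T cells were wild type (WT) or Menin knockout (KO), and were cultured for 5 days with IL-2 at 15 ng/ml and IL-4 at 10 ng/ml, or for longer in a culture named as 3 weeks. Per the labels' protocols, the longer culture was 5 days under the same conditions, 2 days without added cytokines and 5 days of restimulation on immobilized antibody against the T cell receptor, with IL-2 and an antibody against IL-4. These steps add up to less than 3 weeks, and the labels do not say what filled the remaining time. Each of the 4 groups (WT 5-day, KO 5-day, WT 3-week, KO 3-week) held 1 library, taken from the sample titles. How Menin was deleted is not given in the sources used here.

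RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. The deposited values are FPKM (read fragments scaled to transcript length and to library depth), a unit read from Cufflinks in the submitters' processing notes and from the values. The notes name Bowtie 0.12.8, TopHat 1.3.2, Cufflinks 2.0.2 and the genome build mm10, per the submitters' processing notes. Read layout, gene annotation, use of strand and filters are not given in the sources used here. Each file held 23746 lines of a gene symbol and an FPKM value. Of the symbols, 240 stood on more than 1 line (702 lines) and their values were summed, which left 23284 symbols. A single cell of the KO 5-day file held a spreadsheet error mark, and that symbol was left out. No symbol of an antigen receptor segment was matched (0 symbols), so that exclusion in the plan removed nothing.

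Total counts were not stated, so depth was inferred from the values. Low FPKM values of genes with 1 transcript in GENCODE M21 fell at steps of whole reads when a length reduced by 200 bases was used. Within 0.05 of a whole number lay 61.6% of such values under 5.5 reads in the WT 5-day library, 60.4% in KO 5-day, 60.7% in WT 3-week and 60.8% in KO 3-week, against 10% for evenly spread values. The inferred depths were 20.9, 22.7, 23.6 and 21.6 M reads in the same order, and the ratios of low values between pairs of libraries were read from the same steps. These depths are approximate. Counting intervals on a ratio of FPKM values used the reads they imply and the exact Clopper-Pearson 95% interval of a share. They cover counting error only, because 1 library per group shows nothing of the variation between cultures or mice.

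With 1 library per group no contrast within a culture time or a genotype can be tested, no p-value is given, and every difference lacks a replicate check. A model that assumes the same genotype difference at both times would leave 1 residual degree of freedom per gene, and was not fitted. A gene was compared when its mean FPKM over the 4 libraries was at least 1, which held for 10973 symbols. Ratios were taken as log2((a + 1)/(b + 1)), a scale that understates differences of low genes. A gene was counted as at least 2-fold higher or lower where this value was at least 1 in size, and the difference of the genotype contrasts was counted at 4-fold. The 4 contrasts were KO against WT at each time and the longer against the shorter culture in each genotype. The genotype contrasts share no library. For each gene list, the median log2 ratio of its compared members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries.

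The contrasts, the rule of size, 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were Men1, then for each genotype contrast the 12 highest and 12 lowest log2 ratios among compared genes with at least 5 FPKM in either library, for each culture contrast the 8 highest and 8 lowest, for both genotype contrasts together the 10 with the largest smaller ratio in each direction, and for their difference the 6 highest and 6 lowest. MicroRNA, small nucleolar RNA and other short RNA genes were left out of the named genes (165 of the compared symbols). List members may be named as well, and Gata3, Il4, Il5, Il13, Il10, Ifng, Tbx21, Bach2, Ezh2, Bmi1, Cdkn1b and Cdkn2c were always given. Some genes named by these rules are not reported here. Setd1b, Tcrg-C1 and Trdc from the lists had no matching symbol and were not analysed here.

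The steps were tested on simulated counts drawn at the inferred depths, with 200 of 10973 genes changed. For KO against WT at 5 days, 98% of 50 genes changed 4-fold and 0% of 50 genes changed 1.5-fold were counted as at least 2-fold, as were 0 of 10773 unchanged genes. At 3 weeks the corresponding values were 100% of 50, 0% of 50 and 2 of 10773. Of 50 genes changed 3-fold, 98% were counted at 5 days and 86% at 3 weeks. Short lengths were raised to a minimum in the simulation and only counting error was drawn. The values for unchanged genes therefore do not describe short RNA genes or the variation between cultures. Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, 4 other scalings (median of ratios, TPM, upper quartile, quantile normalization), leaving out short RNA genes, fold rules of 1.5 and 4, the highest value for repeated symbols, and random lists without matching. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, and 90.6% of compared symbols were found there. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.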

Results

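Gene expression was measured in Th2 cells grown from splenic CD4 T cells, either wild type (WT) or Menin knockout (KO). Cells were measured after 5 days and in a longer culture named as 3 weeks. Menin is a component of Trithorax group complexes, which act on chromatin, and the libraries address what it does in Th2 cells. There was 1 library in each of the 4 groups, so no value below has a replicate error. Inferred depth was 20.9 M reads in WT 5-day, 22.7 M in KO 5-day, 23.6 M in WT 3-week and 21.6 M in KO 3-week. Across the 10808 compared genes that are not short RNA genes, the WT and KO 5-day libraries had a Pearson correlation of 0.975 and the WT and KO 3-week libraries 0.892, over genes, which are not independent replicates.

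Men1, the gene that encodes Menin (chromosome 19, 6334979 to 6340891, GRCm38), was lower in both KO libraries. It stood at 32.8 FPKM in WT 5-day and 10.3 FPKM in KO 5-day, 31.5% of WT (counting interval 28.8% to 34.4%). In the longer culture it stood at 25.4 FPKM in WT and 5.88 FPKM in KO, 23.1% of WT (20.6% to 26.0%). The direction goes with the genotype labels. Gene-level values do not show which exons the remaining reads came from, nor how complete the deletion was.

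After 5 days, KO cells carried more RNA of cytotoxic granule genes than WT cells. Granzymes are serine proteases and perforin forms pores in target cells. Gzmd stood at 3.27 FPKM in WT and 202 FPKM in KO, Gzmg at 1.92 and 109 FPKM, Gzme at 1.57 and 94.9 FPKM, Gzmf at 0.373 and 24.6 FPKM, Gzmc at 8.96 and 177 FPKM, and perforin (Prf1) at 1.71 and 28.6 FPKM. The 5 granzymes lie together on chromosome 14, from 56117626 to 56234656, and are closely related copies between which the authors' counting could split reads, so each single value is uncertain. Gzmf also overlaps an antisense gene, and whether the counting used strand is not stated. Summed over these 5 copies, FPKM was 16.1 in WT and 608 in KO, 37.8-fold higher. Summed over all 9 listed granzyme genes, most of it from Gzma and Gzmb, FPKM was 1101 in WT and 5277 in KO, 4.79-fold higher. Of 19 compared cytotoxic genes, 13 were at least 2-fold higher and 1 was at least 2-fold lower, the chemokine gene Ccl4 at 3.46 and 0.962 FPKM. The list median was 1.52 on the log2 scale, where the central 95% of random lists spanned -0.14 to 0.16.

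Other genes stood high in KO cells at 5 days. Ifitm1, an interferon-induced membrane protein gene, stood at 19.4 FPKM in WT and 451 FPKM in KO, and S100a4, a calcium-binding protein gene, at 59.6 and 532 FPKM. Fcer1g, the gene of a signalling chain of Fc receptors, stood at 6.11 and 61.3 FPKM, Napsa at 0.825 and 14.6 FPKM, and Trp73, a p53 family gene, at 1.52 and 17.5 FPKM. Gm12238 was listed at 0 in WT 5-day and KO 3-week, at 9.48 FPKM in KO 5-day and at 9.0 FPKM in WT 3-week, but its transcript of 124 bases is shorter than the 200 bases subtracted in the read estimate, so its values are uncertain, like those of short RNA genes. Lower in KO were Igfbp4, a gene of an insulin-like growth factor binding protein, at 527 FPKM in WT and 93.4 FPKM in KO, and the costimulatory gene Cd40lg at 27.2 and 3.36 FPKM. St6galnac2 stood at 11.6 and 0.840 FPKM, Cd6 at 59.5 and 12.1 FPKM, AA465934 at 28.1 and 4.03 FPKM, Stap1 at 8.98 and 1.32 FPKM, Atrnl1 at 10.7 and 2.23 FPKM, and Akr1c18 at 12 and 3.26 FPKM. Tcf7, a transcription factor gene of naive T cells, stood at 61.3 and 12.5 FPKM.

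Of 7 compared Th2 cytokine genes, 6 had a higher and 1 a lower FPKM in KO at 5 days. Il4 stood at 6.41 FPKM in WT and 9.71 FPKM in KO, Il5 at 0.971 and 1.91 FPKM, Il13 at 1.62 and 3.68 FPKM, and Il10 at 22.3 and 32.0 FPKM. Il24 was the lower member, at 11.6 and 7.50 FPKM, 64.8% of WT (counting interval 52.8% to 79.2%). Areg and Csf2 were higher by few reads (ratios 1.47 and 1.71, counting intervals 0.42 to 5.71 and 0.76 to 3.86), so their direction is open. On the log2(FPKM + 1) scale 0 of the 7 were at least 2-fold higher and 0 lower, and the median was 0.50 (random lists -0.21 to 0.26). Random lists were matched on expression over all 4 libraries, and Il5 and Il13 were far lower at 5 days than in WT 3-week. That range may therefore be too narrow at 5 days. The FPKM ratio of Il13 itself was 2.27 (counting interval 1.51 to 3.49), and with a pseudocount of 0.1 it was the 1 of 7 counted as at least 2-fold higher. Gata3, the transcription factor gene that defines Th2 cells, stood at 72.8 FPKM in WT and 69.8 FPKM in KO. Of 16 Th1 genes, 6 were at least 2-fold higher and 0 lower (median 0.56, random lists -0.17 to 0.13), among them the Th1 regulators Tbx21 (8.08 and 20.7 FPKM) and Eomes (1.80 and 8.42 FPKM), while Ifng stood at 0.477 and 0.700 FPKM. Of 14 inhibitory receptor and exhaustion genes 5 were higher, among them Lag3 (4.04 and 15.0 FPKM) and Havcr2 (2.47 and 11.7 FPKM), with a median of 0.68. Of 15 naive and central memory genes 3 were lower, among them Tcf7 and Ccr7 (107 and 41.5 FPKM), with a median of -0.45.

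Over all 10973 compared genes at 5 days, 304 were at least 2-fold higher and 90 at least 2-fold lower in KO. Short RNA genes made up 34 of the higher and 42 of the lower genes, and without them the counts were 270 and 48. Of single genes fixed for every comparison, Bach2 stood at 2.96 FPKM in WT and 1.3 FPKM in KO, 43.9% of WT (counting interval 37.6% to 51.0%), and Ezh2 at 114 and 77.7 FPKM, 68.3% of WT (65.7% to 71.0%). Bmi1 stood at 15.8 and 14.3 FPKM, Cdkn1b at 39.9 and 44.5 FPKM, and Cdkn2c at 27.0 and 24 FPKM. The total of 394 depended on the pseudocount, with 642 genes at a pseudocount of 0.1 and 178 at a pseudocount of 5.

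**Figure D1:**
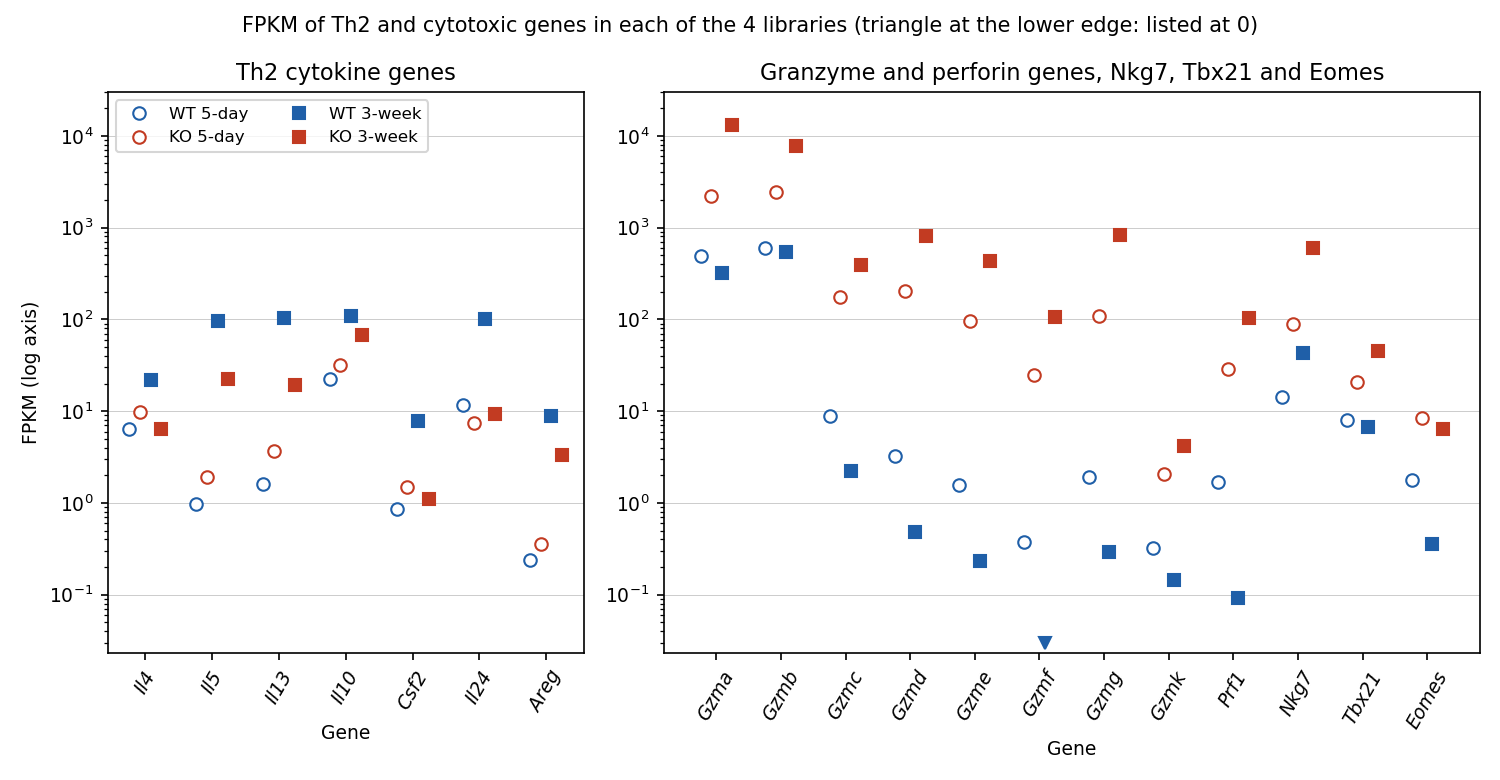
FPKM of the 7 compared Th2 cytokine genes and of granzyme genes, Prf1, Nkg7, Tbx21 and Eomes in each of the 4 libraries, on a log axis, with 1 point per library and no error bars because each group held 1 library. Open circles are 5-day and filled squares 3-week cultures, blue is WT and red is KO, and the triangle marks Gzmf, listed at 0 in WT 3-week; Il13 stands at 105 FPKM in WT 3-week and 19.1 in KO 3-week, and Gzma at 322 and 13071 FPKM.

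In the longer culture the cytotoxic genes stood further apart between the genotypes. Gzma stood at 322 FPKM in WT and 13071 FPKM in KO, Gzmb at 539.7 and 7838 FPKM, Gzmc at 2.21 and 388 FPKM, Gzmd at 0.479 and 811 FPKM, Gzme at 0.235 and 429 FPKM, Gzmg at 0.289 and 829 FPKM, and Prf1 at 0.0912 and 103 FPKM. Gzmf was listed at 0 in WT 3-week and stood at 106 FPKM in KO 3-week. Gzmc to Gzmg, the 5 related copies, summed to 3.22 FPKM in WT and 2563 FPKM in KO, 797-fold higher. The 9 listed granzymes, most of the sum from Gzma and Gzmb, summed to 866 FPKM in WT and 23477 FPKM in KO, 27.1-fold higher, and took 0.186% and 4.91% of all FPKM. Of 19 compared cytotoxic genes, 16 were at least 2-fold higher and 0 lower, with a median of 3.42 (random lists -0.38 to 0.27). Nkg7, a granule membrane gene, stood at 43.5 and 595 FPKM, and the chemokine gene Ccl5 at 47.4 and 286 FPKM.

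Markers of other cell types were measured beside this group. The CD8 gene Cd8a stood at 0.0330 FPKM in WT 5-day, 0.540 in KO 5-day and 0.653 in KO 3-week and was listed at 0 in WT 3-week, and Cd8b1 stood at 2.04 FPKM in WT 3-week and 3.12 FPKM in KO 3-week. The NK cell gene Klrb1c stood at 0.119 FPKM in WT 5-day, 1.51 in KO 5-day, 0.0174 in WT 3-week and 1.96 in KO 3-week. Ncr1, another NK cell gene, was listed at 0 in both WT libraries and stood at 0.244 FPKM in KO 5-day and 0.110 FPKM in KO 3-week. Cd4 stood at 212 FPKM in WT and 307 FPKM in KO, and Cd3e at 206 and 318 FPKM. Of 7 compared myeloid and dendritic cell markers 5 were higher and 1 lower (median 1.99, random lists -0.57 to 0.66), with Fcer1g at 0.186 and 104 FPKM and Itgax at 0.0497 and 8.63 FPKM, while the macrophage gene Lyz2 stood at 0.0989 FPKM in WT and was listed at 0 in KO. At 5 days 3 of these 7 were higher (median 0.91). Of 15 T cell identity genes 1 was higher, Cd3g, and 2 were lower, Cd5 (81.3 and 3.51 FPKM) and Cd28 (70.4 and 32.1 FPKM), with a median of 0.10 (random lists -0.56 to 0.17).

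The Th2 cytokine genes were lower in KO than in WT in the longer culture. Il5 stood at 95.1 FPKM in WT and 22.4 FPKM in KO, 23.6% of WT (counting interval 21.6% to 25.7%). Il13 stood at 105 and 19.1 FPKM, 18.2% of WT (16.4% to 20.2%), and Il4 at 21.9 and 6.40 FPKM, 29.1% of WT (21.3% to 39.3%). Il24 stood at 101 and 9.31 FPKM, Csf2 at 7.73 and 1.11 FPKM, Areg at 8.94 and 3.34 FPKM, and Il10 at 108 and 67.2 FPKM. Of 7 compared members 6 were at least 2-fold lower and 0 higher, with a median of -2.04 (random lists -0.63 to 0.51). Il4, Il13 and Il5 lie on chromosome 11, at 53602982 to 53618669, 53631324 to 53634702 and 53720794 to 53725106. Of 18 Th2 regulators and receptors 9 were lower and 2 higher (median -0.99, random lists -0.51 to 0.14). Gata3 stood at 93.8 and 45.9 FPKM, a log2 ratio of -1.02 that was -0.91 with median-of-ratios scaling and so lay at the 2-fold rule. Irf4, a transcription factor gene of activated T cells, stood at 67.9 and 5.09 FPKM, and Il1rl1, the gene of the IL-33 receptor, at 14.9 and 5.32 FPKM, whereas Ecm1 stood higher at 118 and 474 FPKM.

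Most Th1 genes (12 of 16) and all 18 compared interferon-stimulated genes had a higher FPKM in KO 3-week than in WT 3-week. Of 16 Th1 genes 10 were at least 2-fold higher and 1 lower (median 1.19), with Tbx21 at 6.68 FPKM in WT and 45.3 FPKM in KO, Ifng at 0.168 and 6.03 FPKM, Eomes at 0.360 and 6.36 FPKM, and Il12rb2, a chain of the IL-12 receptor, at 3.51 and 41.7 FPKM. The lower member was Lta, at 29.4 and 2.5 FPKM. Of 18 interferon-stimulated genes 12 were higher and 0 lower (median 1.55, random lists -0.37 to 0.30), with Isg15 at 2.44 and 36.8 FPKM and Irf7 at 5.43 and 40.4 FPKM.

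Part of the cell cycle, glycolysis and cholesterol synthesis lists was at least 2-fold lower in KO 3-week. Of 35 cell cycle genes 12 were at least 2-fold lower and 0 higher (median -0.89, random lists -0.46 to 0.03), among them Top2a (172 and 76.9 FPKM) and Rrm1 (106 and 40.1 FPKM). Of 19 glycolysis genes 6 were at least 2-fold lower and 0 higher, and 4 lay above 0 (median -0.79), among them Hk2 (11.2 and 2.58 FPKM) and Ldha (832 and 363 FPKM). Of 18 cholesterol synthesis genes 7 were at least 2-fold lower and 0 higher, and 3 lay above 0 (median -0.80), among them Sqle (23.9 and 4.95 FPKM). The polycomb list had a median of -0.11, inside the random lists' range and above 0 at 0.07 with upper-quartile scaling, but 5 of its 28 genes were lower and 1 higher. Ezh2, the histone methyltransferase gene of that group, stood at 93.6 and 27.3 FPKM and Suz12 at 36.3 and 16.7 FPKM, while Bmi1 stood at 13.4 and 12.8 FPKM. None of 19 MLL and trithorax complex genes, a list without Men1, reached 2-fold at either time (0 higher, 0 lower, medians -0.16 and -0.27). Bach2 stood at 0.712 and 0.384 FPKM, Cdkn1b at 25.2 and 46.0 FPKM, and Cdkn2c at 16.6 and 17.6 FPKM.

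Other genes stood far apart between the genotypes at 3 weeks. Higher in KO were Trf, which encodes transferrin, at 0.258 FPKM in WT and 62.5 FPKM in KO, the Fc receptor gene Fcgr3 at 0.624 and 72.8 FPKM, Tmem158 at 0.745 and 74.5 FPKM, and Ifitm1 at 49.1 and 1913 FPKM. Lower were Igfbp4 at 115 and 0.372 FPKM, the lymph node homing receptor gene Ccr7 at 75.3 and 2.45 FPKM, Cd6 at 52.2 and 1.99 FPKM, Akr1c18 at 204 and 8.96 FPKM, and Cd40lg at 59.5 and 3.57 FPKM. The cytokine gene Lif stood at 67.5 and 3.04 FPKM, Msc at 78.5 and 4.09 FPKM, Batf3 at 36.7 and 1.63 FPKM, and Htr1b at 47.0 and 2.98 FPKM. Over the 10973 compared genes, 874 were at least 2-fold higher and 899 lower, 49.3% higher. With upper-quartile scaling the split was 1120 higher and 575 lower, 66.1% higher, because that scaling moved the median log2 ratio of all genes from -0.08 to 0.08.

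Genes that stood apart at 5 days mostly stood apart in the same direction at 3 weeks. At least 2-fold higher in KO at both times were 216 genes, where 24.2 would overlap in independent lists, and 44 were lower at both times, where 7.37 would. In opposite directions stood 26 genes (15 higher then lower, 11 lower then higher). Short RNA genes accounted for 18 of these, and without them 208 were higher at both times, 30 lower at both times and 8 opposite. The log2 ratios at the 2 times had a Pearson correlation over genes of 0.433, and 0.718 without short RNA genes. Besides the granzymes, Prf1, Ifitm1, Fcer1g and Napsa, the rule for both times named Col18a1, at 3.06 and 24 FPKM at 5 days and 7.40 and 127 FPKM at 3 weeks. On the lower side it named St6galnac2, Cd40lg, AA465934, Igfbp4, Cd6, Stap1, Atrnl1, 1700025K23Rik, Akr1c18 and A430093F15Rik. These contrasts share no library, but genes are not replicates and no test was made.

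**Figure D2:**
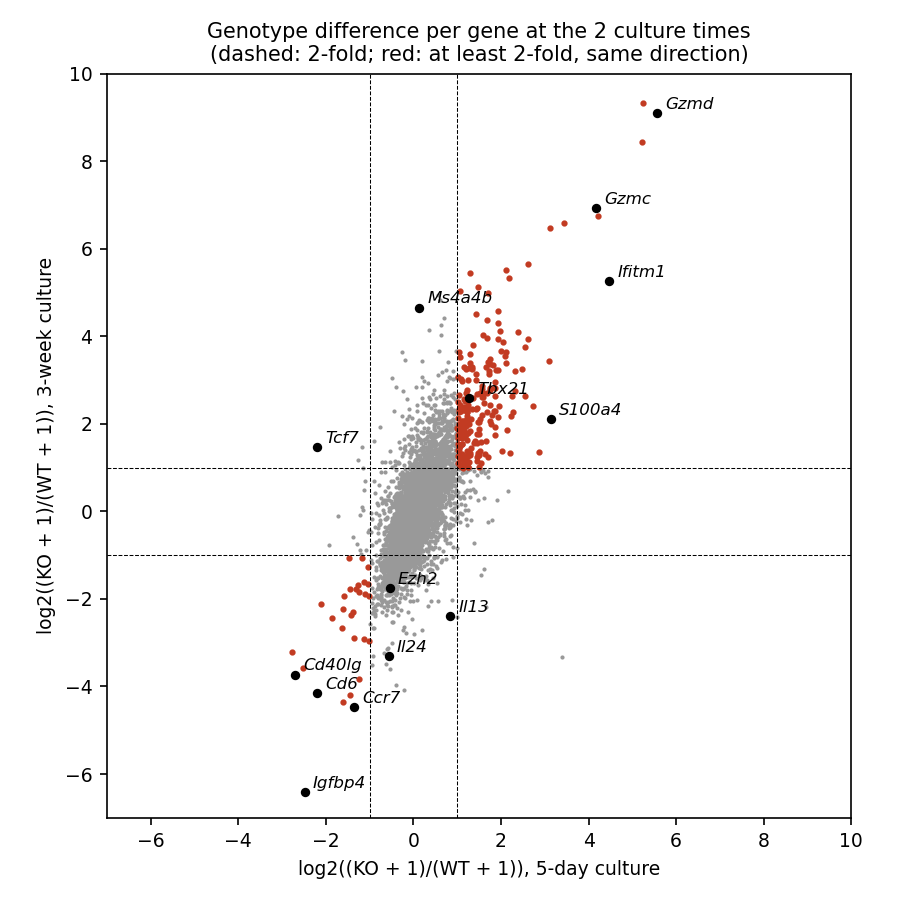
Each point is 1 of 10808 compared genes (short RNA genes left out), placed by its log2((KO + 1)/(WT + 1)) ratio of FPKM at 5 days on the horizontal axis and at 3 weeks on the vertical axis, with dashed lines at 2-fold. Red points are the 238 genes at least 2-fold apart in the same direction at both times, black points are labelled genes, and Il13 sits at 0.84 and -2.40.

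The genotype difference itself differed by at least 4-fold between the 2 times in 224 genes, 138 with a higher and 86 with a lower KO to WT ratio at 3 weeks. Without short RNA genes the counts were 87 and 41, 128 in total. Ms4a4b stood at 40.5 FPKM in WT 5-day, 44.2 in KO 5-day, 1.70 in WT 3-week and 67.0 in KO 3-week. Cd7, a T and NK cell surface gene, stood at 3.43, 5.77, 0.857 and 52.1 FPKM in the same order, Gm4070 at 12.3, 18.8, 2.08 and 92.9 FPKM, and Hgfac at 0.478, 2.08, 0.178 and 37.6 FPKM. On the lower side were Igfbp4, Lif, Msc, S100a5 and Cox6b2. The difference was at least 2-fold lower in all 7 compared Th2 cytokine genes (7 of 7, median -2.46), and at least 2-fold higher in 16 of 19 cytotoxic genes (median 2.52) and 11 of 18 interferon-stimulated genes (median 1.16). It was not tested.

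In WT cells the longer culture had more Th2 cytokine RNA and less RNA of naive T cell genes than the 5-day culture. The 2 cultures also differed in restimulation and in the cytokines and antibody present. Il5 stood at 0.971 FPKM after 5 days and 95.1 FPKM in the longer culture, Il13 at 1.62 and 105 FPKM, and 7 of 7 compared Th2 cytokine genes were at least 2-fold higher (median 3.00). Msc stood at 2.78 and 78.5 FPKM, Akr1c18 at 12 and 204 FPKM, Htr1b at 4.50 and 47.0 FPKM, Ctsh at 1.25 and 22.6 FPKM, and S100a4 at 59.6 and 635 FPKM. Of 15 naive and central memory genes 10 were lower and 0 higher (median -1.25), among them Tcf7 (61.3 and 0.0622 FPKM) and Klf2 (78.6 and 3.64 FPKM). Of 19 cytotoxic genes 7 were at least 2-fold lower and 2 higher (median -0.41, random lists -0.16 to 0.18), and of 18 interferon-stimulated genes 1 was lower and 1 higher, with 13 below 0 (median -0.65, random lists -0.17 to 0.19). Ly6c2 stood at 59.5 and 2.65 FPKM, Fads2 at 24.7 and 0.582 FPKM, Add3 at 54.8 and 2.58 FPKM and St3gal6 at 16.9 and 0.273 FPKM. In all, 332 genes were at least 2-fold higher and 311 lower, 643 in total, and with a mean filter of 5 FPKM the total was 421.

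In KO cells the longer culture had more cytotoxic and interferon-stimulated RNA and less cell cycle RNA than the 5-day culture. Of 19 cytotoxic genes 13 were at least 2-fold higher and 0 lower (median 1.70), and of 18 interferon-stimulated genes 10 were higher (median 1.11). Of 35 cell cycle genes 18 were lower (median -1.0), against 1 of 35 in WT (median -0.30). Of 7 Th2 cytokine genes 4 were higher (median 1.05), with Il5 at 1.91 FPKM after 5 days and 22.4 FPKM in the longer culture and Il4 at 9.71 and 6.40 FPKM. Tmem158 stood at 1.69 and 74.5 FPKM, Hgfac at 2.08 and 37.6 FPKM, the complement receptor gene C5ar1 at 0.559 and 20.7 FPKM, Ramp3 at 3.88 and 57.5 FPKM, Esm1 at 4.0 and 54.1 FPKM, Upp1 at 0.994 and 19.2 FPKM, Nov at 1.12 and 19.9 FPKM and Ccl9 at 0.0626 and 9.38 FPKM. Igfbp4 stood at 93.4 and 0.372 FPKM, Cd24a at 51.8 and 2.20 FPKM, Trat1 at 55.2 and 2.69 FPKM, Ccr7 at 41.5 and 2.45 FPKM and Cd5 at 40.7 and 3.51 FPKM. In all, 477 genes were higher and 482 lower.

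Of 58 list medians in the genotype contrasts (29 lists with a compared member, 2 times), 26 lay outside the central 95% of their random lists, where 2.9 would by chance. Lists not described above had the following medians at 5 days and at 3 weeks. Treg genes had 0.39 and -0.23, Tfh genes -0.48 and -0.70, apoptosis regulators 0.10 and 0.10, histone genes -0.25 and 0.18, immediate early activation genes -0.08 and 0.46, and cyclin-dependent kinase inhibitors 0.13 and 0.11. Inhibitory receptor and exhaustion genes had 0.30 at 3 weeks, with 6 of 14 higher and 1 lower, and naive and central memory genes had -0.09, which was 0.10 with upper-quartile scaling. Secreted senescence factors had -0.01, with a sign that turned under other scalings, and 0.51. Housekeeping genes had -0.13 and -0.39, with Hprt the 1 of 12 that was at least 2-fold lower at 3 weeks (119 and 50.6 FPKM). Lists with 3 or fewer compared members were stromal markers (0.03 and -0.37), mast cell and basophil markers (1.15 and 1.41), Rora of the Th17 list (0.81 and 0.36), Pbx3 of the Hox A and Meis list (0.16 and 0.11), Cd8b1 (0.20 and 0.44), Hba-a1 of the erythroid list (-1.13 and 0.48) and Xist of the sex-linked list (-0.25 and -0.74). The mast cell and basophil list had 2 compared members, which went opposite ways at 3 weeks (1 above 0, 1 below 0). B cell markers and NK and gamma delta T cell markers had 0 compared members.

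**Figure D3:**
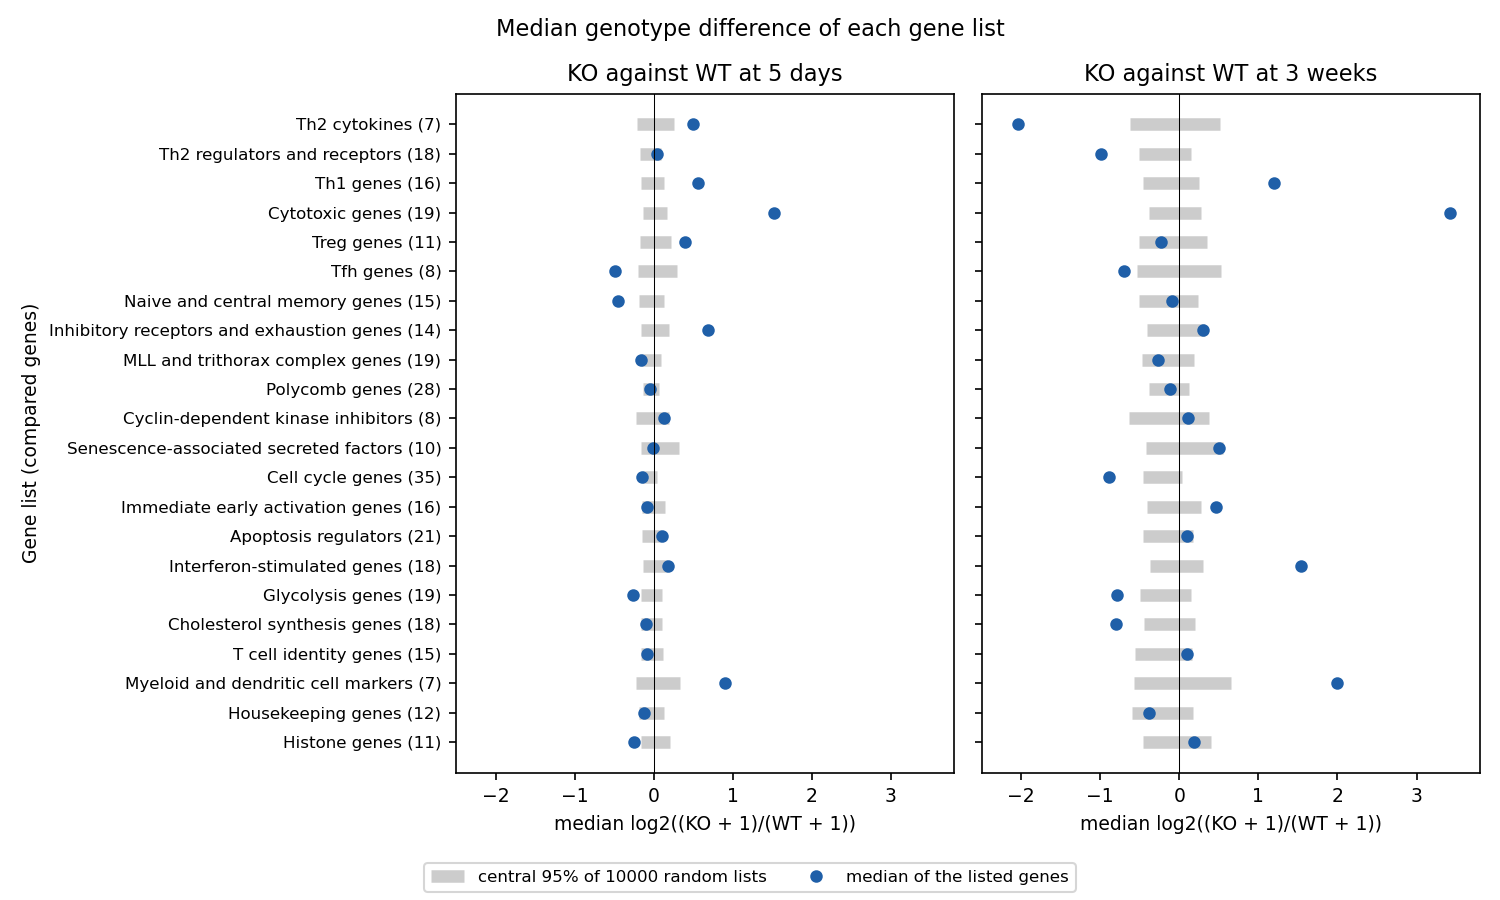
Median log2((KO + 1)/(WT + 1)) ratio of FPKM for the 22 gene lists with at least 5 compared members (number in parentheses), at 5 days on the left and 3 weeks on the right. Blue points are the listed genes and grey bars the central 95% of medians of 10000 random lists of the same size and expression; the cytotoxic median is 1.52 and 3.42, and the Th2 cytokine median 0.50 and -2.04.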

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

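Among lists with both medians outside the random range, only the Th2 cytokine list ran in opposite directions at the 2 culture times. Some other medians, such as those of the Treg and histone lists, also changed sign. With short RNA genes left out, the genotype difference was at least 2-fold and opposite in 8 genes (Ccl4, Tcf7, Nt5e, Cox6b2, Ctsh, Mt3, S100a5 and Gm12238). Each group held 1 library, and none of these differences was tested. The cytotoxic list, by contrast, had a median above 0 at both times (1.52 and 3.42), with Ccl4 as its 1 member at least 2-fold apart both ways. The tests on library scaling and shared granzyme reads were chosen after the values were seen. So were those on CD8 T cells against the Cd4 level and on NK cells in place of CD4 T cells. The use of the SD over list members in the tests on the receptor stimulus and T cell loss was also chosen then. That SD is a spread over genes and not an error of the median, and the 2 tests used it differently.

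The median of the Th2 cytokine genes was 0.50 at 5 days and -2.04 at 3 weeks on the log2 scale, a difference of contrasts with a list median of -2.46. The 5-day side rests partly on low values, and counting intervals left the direction of Areg and Csf2 open there. Library scaling does not account for the lower cytokine RNA in KO 3-week, since the highest median under 4 other scalings was -1.85, with an SD over the 7 genes of 0.85. Fewer T cells in that culture would lower T cell transcripts by about as much as the cytokines. The T cell identity list had a median of 0.10 (SD 1.28), which is 2.13 above the cytokine median. That gap was larger than the SD. For the receptor stimulus the SD was set against the distance from the bound set beforehand. By that rule T cell loss would stay undecided too, so a smaller loss is not excluded. The values of these 2 libraries argue against a loss as large as the cytokine difference. Of the 15 identity genes 12 lay within 2-fold, 1 was at least 2-fold higher and 2 lower, and 9 lay above 0. A weaker receptor stimulus cannot be told apart from other causes: the immediate early list had a median of 0.46 (SD 1.55), above the bound set beforehand by less than that SD, and its members went both ways, with Irf4, Myc and Nr4a1 lower and Jun, Cd69 and Tnfaip3 higher. An effect of Menin loss and any other difference between the 2 cultures stay open, the former as a hypothesis that 1 library per group cannot test.

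Shared reads between granzyme copies do not account for the higher cytotoxic RNA in KO 3-week, since moving reads between copies leaves a sum in place and the sum of the related copies Gzmc to Gzmg was 797-fold higher. NK cells in place of most CD4 T cells do not either, since Cd4 was 1.45 times as high as in WT and Cd3e was higher still. The test on CD8 T cells or NK cells in the KO culture that was set before the values were seen gave the outcome predicted for such cells. It did so through Klrb1c at 1.96 FPKM, over the limit of 1 FPKM, while Ncr1 stood at 0.110 FPKM. Of the myeloid list Fcer1g, Tyrobp and Itgax, which NK cells also express, were higher. The cultures started from CD4 T cells, a selection that would remove most NK cells. A smaller number of NK cells, or T cells with NK receptors, may still contribute. CD8 T cells cannot be told apart from other sources: Cd8a was listed at 0 in WT 3-week and stood at 0.653 FPKM in KO 3-week, 0.213% of the Cd4 level, while Cd8b1 stood at 0.961% of that level in WT and 1.02% in KO, between the bounds of 1% against and 10% for such cells, and how much of these chains CD8 T cells would carry here was not measured. Expression by the CD4 T cells themselves stays open as an untested hypothesis.

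The chemokine gene Ccl4 stood at 3.46 FPKM in WT 5-day, 0.962 in KO 5-day, 5.27 in WT 3-week and 16.5 in KO 3-week, a difference of contrasts of 2.66, and belongs to the cytotoxic list. Tcf7 stood at 61.3 and 12.5 FPKM in WT and KO at 5 days and at 0.0622 and 1.95 FPKM at 3 weeks, a difference of contrasts of 3.68. Nt5e stood at 5.57 and 1.74 FPKM, then 0.387 and 2.10 FPKM (2.42). Cox6b2 stood at 10.9 and 22.8 FPKM, then 19.3 and 2.84 FPKM (-3.40). Ctsh stood at 1.25 and 5.87 FPKM, then 22.6 and 8.49 FPKM (-2.93). Mt3 stood at 8.58 and 26.9 FPKM, then 40.5 and 14.2 FPKM (-2.99). S100a5 stood at 1.47 and 6.73 FPKM, then 13.7 and 2.22 FPKM (-3.83). Gm12238 also went both ways but was listed at 0 in 2 libraries, so no difference is given.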

How the results depend on the processing

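Of 85 counts recomputed under the alternatives, 62 stayed within 1.5 times the reported count, and the number of list medians outside their random range, 26 as reported, lay between 23 and 29. The fold rules do not enter that number. The other 23 moved by more. For the fold rules, the filter and the short RNA genes this follows from how many genes each admits. A larger pseudocount makes log2 ratios smaller in size, so fewer genes of a contrast pass the rule. For the difference of contrasts that cause was not tested. With a pseudocount of 0.1 the KO against WT total at 5 days was 642 (394 as reported), genes in the same direction at both times 445 (260), and genes with a difference of contrasts 398 (224). With a pseudocount of 5 the totals were 178 at 5 days, 898 at 3 weeks (1773), 276 for the culture contrast in WT (643), 468 for that in KO (959), 101 for both times and 132 for the difference. The 1.5-fold rule gave 1063, 3980, 1537, 2443, 777 and 716 in the same order, and the 4-fold rule 103, 406, 157, 200, 45 and 85. A mean of at least 5 FPKM gave 421 for the culture contrast in WT, and leaving out short RNA genes gave 128 for the difference. Of 126 log2 ratios of named genes under other pseudocounts and scalings, 8 crossed the 2-fold rule in at least 1 setting, among them Gata3 at 3 weeks (-0.82 with upper-quartile scaling), and no ratio past the 2-fold rule changed sign. Of 58 list medians 14 crossed the edge of their random range in at least 1 setting, and of those outside their range as reported 1 changed sign: the erythroid list at 5 days had a median of 0.0154 with no filter, where 7 members in place of 1 were compared. Some medians inside their range also changed sign, among them the polycomb, naive and sex-linked lists at 3 weeks. The groups share only 1 replicate number, so no block by that number was fitted. A fit pairing KO with WT by culture time, which assumes the same genotype difference at both times, is possible but was not run. Depth limits single low values: 4-fold differences were recovered in 98% (5 days) and 100% (3 weeks) of 50 simulated genes, which covers counting error only. For 3-fold differences the shares were 98% (5 days) and 86% (3 weeks) of 50.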

Other observations

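The tests in this part were chosen after the values were seen. Some genes that lie close together on a chromosome stood lower in KO together. On chromosome 19, Cd5 (10717116 to 10739002), A430093F15Rik (10740947 to 10786043) and Cd6 (10789341 to 10830058) were all lower in KO at both times, with log2 ratios of -1.44, -1.60 and -2.21 at 5 days and -4.19, -2.23 and -4.15 at 3 weeks. Fads2 (10062765 to 10101746) and Ms4a4b (11443553 to 11467055), on either side of them, were higher in KO at 3 weeks. Their log2 ratios were 0.09 and 0.13 at 5 days and 2.42 and 4.66 at 3 weeks. On chromosome 11, Igfbp4 (99041244 to 99054392) and Ccr7 (99144196 to 99155077) had -2.48 and -1.35 at 5 days and -6.40 and -4.47 at 3 weeks. On chromosome 3, the nearby genes S100a4 and S100a5 were both higher in KO at 5 days (3.14 and 1.65), but went apart at 3 weeks (2.11 and -2.19). These groups were picked from their values, and how often nearby genes go together by chance was not tested. Men1, the deleted gene, also lies on chromosome 19 (6334979 to 6340891). Whether its position bears on the values of Cd5, A430093F15Rik and Cd6 was not tested.

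Further list members were chosen here after their values were seen. Of 21 apoptosis regulators in the 3-week libraries, 2 were at least 2-fold higher and 4 lower in KO, with a median of 0.10 inside the range of random lists (-0.46 to 0.17). Among them, Bcl2l11 stood at 1.47 FPKM in WT and 9.54 FPKM in KO, and Bcl2 at 29.2 and 13.1 FPKM. Of 8 cyclin-dependent kinase inhibitors 1 was at least 2-fold higher and 0 lower (median 0.11), with Cdkn2b at 2.52 and 20.7 FPKM and Cdkn2a at 49.9 and 49.7 FPKM. Spp1, which encodes osteopontin, stood at 14.7 and 58.7 FPKM at 5 days and 44.2 and 424 FPKM at 3 weeks. The IL-2 receptor gene Il2ra stood at 638 FPKM in WT 3-week and 152 FPKM in KO 3-week.

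A hypothesis is that the genotype difference is larger in the longer culture. Of 318 genes at least 2-fold apart at 5 days (short RNA genes left out), 206 (64.8%) were further from 0 in the same direction at 3 weeks, although picking genes for their 5-day value favours larger values there. The values are consistent with a difference that is larger in the longer culture, but they may as well come from the KO 3-week library alone, which differed most from the other libraries, and 1 library per group cannot tell these apart.

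Short RNA genes, such as microRNA and small nucleolar RNA genes, were at least 2-fold apart far more often than other genes in every contrast. In WT 3-week against WT 5-day, 44.8% of 165 were, against 4.58% of other genes of the same mean FPKM, a ratio of 9.80. Lengths shorter than a sequenced fragment may produce this, since FPKM then divides by a length near 0. The ratio was over the limit of 3 set for that explanation after the values were seen. It restates the excess that prompted the test and cannot separate short lengths from other causes. No biological explanation was tested.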
